A study of Mus musculus with 8 samples.

How the data were processed

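The measurements were gene expression values from 8 paired-end, polyA-enriched RNA libraries of mouse mammary spheroids, 2 in each of 4 groups taken from the sample titles. Per the submitters' processing notes, the authors used Cufflinks and the GRCm38 genome. The Cufflinks version, the aligner and the annotation release are not given in the sources used here. Each deposited file held 1 library, with a gene symbol, a locus, an FPKM value (fragments scaled to transcript length and to the size of the library) and lower and upper confidence bounds of that FPKM, per the file headers. FPKM divides by gene length and library total, so a few very abundant transcripts lower all other values of a library, and transcripts shorter than the fragments can reach very large values. Cufflinks also assigns fragments that match several loci among them, which leaves paralogs uncertain, and the use of strand in counting is not given in the sources used here.

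Each file had 27040 entries. The 404 entries without a symbol, 7 second loci of a symbol and 154 genes with a status other than OK in any library were left out, which kept 26475 genes. The 13499 genes at 1 FPKM or more in at least 2 of the 8 libraries were tested, 111 of which span under 200 bases. Coordinates are those of the files, 1-based on GRCm38. Of the tested symbols 11851 were found in GENCODE M21, which uses the same build, and 99.9% of those overlapped the annotated locus. The files hold no read counts. The confidence bounds gave an effective fragment number per gene, the square of 2 times the FPKM divided by the distance from the FPKM to its upper bound. Among numbers under 20, between 76.7% and 78.7% per library lay within 0.02 of a whole number. Their sum was taken as the depth of a library, between 10945700 and 23838695 fragments, and the median over tested genes lay between 220.0 and 591 fragments. They were not used as counts in any test.

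Values were compared as log2(FPKM + 1) with no further scaling. A fold change on this scale understates changes of genes near 1 FPKM. A linear model with 4 group means over all 8 libraries, which leaves 4 residual degrees of freedom, was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean-dependent trend. The contrasts were Mtdh-KO against control tumorspheres, C26A6 against control mammospheres, the difference between these changes, and control tumorspheres against control mammospheres. All tests were two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. Group values are means ± SD of 2 libraries in FPKM, and folds are ratios of those means. Of 35 gene lists of pathways and cell types, fixed with the tests and the rule for naming genes before the data were examined, the 32 with at least 5 tested members were tested with camera in limma at a preset inter-gene correlation of 0.01, which compares a list with all other genes, with an estimated correlation as an alternative and fry beside it. The other 3 lists had too few tested members, in part because the 9 symbols of mitochondrial transcripts matched no entry. Older symbols in the files were matched through a gene name table. The list tests of the baseline and of the difference were added later. The estimated correlation called 0 lists in any comparison, including the baseline fibroblast list, all 10 tested members of which passed singly. Failing that alternative therefore says little about a list here. Passing at the preset 0.01 can also mislead. The estimated correlations were 0.46 for hypoxia, 0.45 for heat shock, 0.33 for cholesterol synthesis and 0.23 for NRF2 targets. Fry, which rests on the spread between libraries, did call the baseline fibroblast list (adjusted p = 3.8e-05).

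Genes were named by a rule. Mtdh, Snd1, Tap1 and Tap2 were always reported. From the called genes with a mean of 5 FPKM or more in a compared group, the libraries of both groups separated and no predicted, RIKEN or pseudogene name, the 10 largest rises and 10 largest falls were taken. From each list up to 4 tested members with the smallest p were taken. Many of the largest changes were of genes listed at exactly 0 or of small RNAs, so the text leads with the same ranking over genes with no value of 0 in the compared libraries, at least 200 bases and no name of a small RNA or unnamed locus, a restriction chosen after the data were seen. A value of exactly 0 can be a failed estimate in these files, since Ubc and Actg1 are listed at 0 in some libraries.

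The alternatives were a pseudocount of 0.1, no filter, a filter of 5 FPKM, median-of-ratios scaling, quantile normalization, a fit of only the 4 libraries compared, the replicate number as a block, and each library left out. After the data were seen, fits without genes listed at 0 and without genes under 200 bases were added. Ranges and lost calls of lists over these settings are at the preset correlation. The steps were tested on simulated data with 200 of 13499 genes changed in each comparison and noise independent between genes. The changed genes were drawn from those above about 5 FPKM in the control group, and the noise was normal with the moderated spread of the fit. The recovery therefore does not cover genes at lower values or listed at 0. For the Mtdh-KO comparison 21% of genes changed by 1 log2 unit and 90% of those changed by 2 were recovered, and 5.93% of calls were unchanged genes. For the C26A6 comparison the values were 26%, 90% and 7.94%. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.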

Results

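Polyadenylated RNA was sequenced as paired-end libraries from mouse mammary cells of the FVB/N strain grown without attachment in serum-free medium, where they form floating spheroids. Tumor cells came from mammary tumors of mice carrying the polyoma middle T oncogene (PyMT) under the mouse mammary tumor virus promoter, a tamoxifen-inducible Cre recombinase (UBC-CreERT) and floxed Mtdh alleles. Their spheroids are called tumorspheres here. Spheroids of normal mammary epithelial cells are called mammospheres. The 8 libraries formed 4 groups of 2, each sampled after 5 days: control tumorspheres, tumorspheres in which 0.02 µg/ml of 4-hydroxytamoxifen was given to delete Mtdh (Mtdh-KO), control mammospheres, and mammospheres given 200 µM C26A6, a compound that the labels describe as disrupting the binding of Mtdh to Snd1. Controls received corn oil and saline. The labels of the normal cells conflict, since the growth protocol names virgin FVB/N mice while the genotype label gives UBC-CreERT with floxed Mtdh. Nothing in the labels says whether the 2 libraries of a group came from separate cultures or animals. The p-value of a single gene therefore measures only the spread between these samples, which may be technical. A camera p-value at the preset correlation of 0.01 rests instead on the spread between genes, taken as nearly independent. Estimated correlations were 0.46 for the hypoxia list, 0.56 for interferon and 0.61 for MHC class I. Camera p-values at the preset can therefore be far too small.

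The deposited confidence bounds gave an effective number of fragments of 14210823 and 18453506 in the control tumorspheres, 10945700 and 11430090 in the Mtdh-KO tumorspheres, 20988973 and 21626443 in the control mammospheres, and 23838695 and 20267338 in the C26A6 mammospheres. Although the Mtdh-KO libraries had the lowest totals, 16172 and 17013 genes had a value above 0 in them, against 14482 and 14271 in the control tumorspheres. The correlation between the 2 libraries of a group, across 13499 genes on the log2 scale, lay between 0.937 and 0.962. The first principal component held 62.9% of the variance and parted all 4 tumorsphere from all 4 mammosphere libraries, and the second held 14.4%. The mammospheres also held transcripts of leukocytes, which were near 0 in the tumorspheres. Ptprc, the pan-leukocyte antigen CD45, stood at 33.1 and 32.7 FPKM in the control mammospheres and at 53.7 and 29.1 FPKM after C26A6, against at most 0.5399 FPKM in any tumorsphere library. The T cell receptor component Cd3e stood at 34.5 and 23.6 FPKM in the control mammospheres and at 92.2 and 31.0 FPKM after C26A6.

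Mtdh, the targeted gene (chromosome 15, 34082719 to 34142385, GRCm38), was measured first, as a check of the labels. It fell from 217 ± 28.4 FPKM in the control tumorspheres to 62.5 ± 0.642 FPKM in the Mtdh-KO tumorspheres (mean ± SD, n = 2), which is 28.9% of control (log2 change -1.77, SE 0.23, limma adjusted p = 0.013). The floxed exons are not stated in the labels, so the remaining signal may include transcripts of the exons outside the deletion. Values per gene do not show how complete the deletion was. The call was lost without control library 2 (adjusted p = 0.082), Mtdh-KO library 1 (0.057) or Mtdh-KO library 2 (0.090), with changes of -1.64, -1.78 and -1.76, and over all settings run the adjusted p lay between 0.0090 and 0.090. In the mammospheres Mtdh stood at 163 ± 13.8 FPKM in the controls and 149 ± 44.5 FPKM after C26A6 (log2 change -0.16, adjusted p = 0.78), which did not pass the test. Snd1, which encodes the binding partner (chromosome 6, 28480348 to 28888832), stood at 16.6 ± 1.25 FPKM in control and 17.9 ± 3.18 FPKM in Mtdh-KO tumorspheres (log2 change 0.10, adjusted p = 0.88), and at 13.9 ± 3.59 and 23.01 ± 5.39 FPKM in control and C26A6 mammospheres (log2 change 0.70, adjusted p = 0.36). Neither difference passed the test, and the sign of the tumorsphere difference turned with the scaling.

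**Figure D1:**
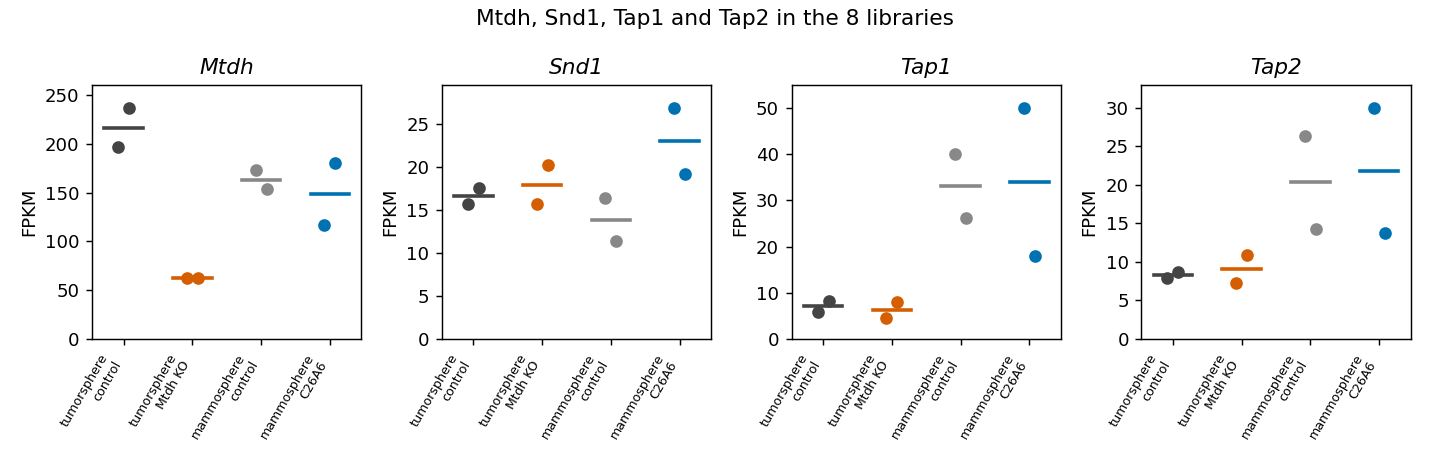
Expression of Mtdh, Snd1, Tap1 and Tap2 in each library, in FPKM on linear axes that start at 0, where points are single libraries and bars are means of the 2 libraries of a group. Mtdh stood near 62.5 FPKM in both Mtdh-KO libraries against a control mean of 216.7 FPKM, and no difference between treated and control libraries passed the test for the other genes shown.

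The first comparison asked which transcripts differ between tumor cells given 4-hydroxytamoxifen to delete Mtdh and their controls. No other group received that drug. Changes in this comparison therefore cannot be told apart from effects of tamoxifen or Cre activation. Hypoxia and glycolysis genes were lower in the Mtdh-KO tumorspheres, with 18 of 19 tested members below control and a median log2 change of -1.49 (camera adjusted p = 8.8e-17; adjusted p = 0.50 with an estimated correlation). Of these, 8 passed the test gene by gene over all genes, and 14 when adjusted over the list alone, all of them lower. Bnip3, a hypoxia-induced mitophagy receptor, fell from 748 ± 184 to 126 ± 61.9 FPKM (log2 change -2.63, SE 0.38, adjusted p = 0.019). P4ha1, a subunit of collagen prolyl hydroxylase, fell from 53.2 ± 17.5 to 11.9 ± 3.98 FPKM, and the glycolytic enzyme Gapdh fell from 3464 ± 1293 to 863 ± 73.5 FPKM. Egln3, an oxygen-sensing prolyl hydroxylase, fell from 122 ± 6.68 to 53.7 ± 0.119 FPKM. Outside the list, Ero1l, an oxidase that forms disulfide bonds in the endoplasmic reticulum, fell 10.9-fold from 2069 ± 1029.8 to 189 ± 145 FPKM (adjusted p = 0.024).

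Heat shock, NRF2 and cholesterol synthesis genes were higher in the Mtdh-KO tumorspheres. All 14 tested heat shock genes lay above control (median log2 change 0.80, camera adjusted p = 1.3e-04; adjusted p = 0.50 with an estimated correlation), and 6 passed the test, or 8 when adjusted over the list alone. Hspa1a, an inducible HSP70 chaperone, rose from 8.01 ± 2.55 to 137 ± 91.6 FPKM (log2 change 3.78, SE 0.55, adjusted p = 0.019), and the small heat shock protein gene Hspb1 rose from 4.88 ± 2.96 to 57.5 ± 25.5 FPKM. Hsph1, a co-chaperone, rose 2.96-fold (adjusted p = 0.011). Cryab, which encodes a further small heat shock protein, rose from 3.41 ± 2.79 to 28.96 ± 2.01 FPKM. Of 15 tested targets of NRF2, the transcription factor of the oxidative stress response, 13 lay above control (median log2 change 1.14, camera adjusted p = 2.0e-04; adjusted p = 0.50 with an estimated correlation) and 8 passed the test, or 9 when adjusted over the list alone. Nqo1, a quinone reductase, rose 3.97-fold to 88.2 ± 27.7 FPKM, and Gclm, a subunit of the enzyme that starts glutathione synthesis, rose 3.69-fold to 75.7 ± 3.71 FPKM. All 18 tested cholesterol synthesis genes lay above control (median log2 change 0.93, camera adjusted p = 9.8e-05; adjusted p = 0.50 with an estimated correlation), of which 4 passed the test, or 13 when adjusted over the list alone. Cyp51, a sterol demethylase, rose from 9.57 ± 4.13 to 30.3 ± 2.98 FPKM, Idi1 rose 2.06-fold and Sqle, which makes squalene epoxide, rose 2.13-fold.

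On the log2(FPKM + 1) scale, the largest rise among called genes with a value above 0 in every compared library was that of the metallothionein Mt2 (chromosome 8, 94172618 to 94173567), from 19.5 ± 3.06 to 630.2 ± 113 FPKM (32.3-fold, log2 change 4.94, SE 0.24, adjusted p = 9.4e-05). Its neighbor Mt1 rose from 90.5 ± 41.6 to 892 ± 139 FPKM. Cyp1b1 (chromosome 17, 79706953 to 79715041), a cytochrome P450 induced by the aryl hydrocarbon receptor, rose from 39.6 ± 11.4 to 275 ± 46.1 FPKM (adjusted p = 0.0029). Acot1, an acyl-CoA thioesterase, rose 9.45-fold, the kinase gene Aatk 15.8-fold, the prostaglandin D synthase gene Ptgds 44.6-fold from a control mean of 0.195 FPKM, and the histone gene Hist1h3e 12.04-fold. The largest fall on that scale was that of the milk protein gene Csn1s1 (chromosome 5, 87666224 to 87682574), from 3811 ± 2664 to 198 ± 141 FPKM (log2 change -4.27, SE 0.60, adjusted p = 0.018). Cxcl5 (chromosome 5, 90759299 to 90761625), a chemokine that attracts neutrophils, fell from 165 ± 48.2 to 17.5 ± 6.61 FPKM (adjusted p = 0.0029), and Cxcl15 fell 10.2-fold. Arg1, which hydrolyses arginine, fell 8.12-fold and the acute-phase gene Saa1 16.9-fold. Wif1, which encodes a secreted Wnt inhibitor, fell from 22.6 ± 3.14 to 2.698 ± 0.571 FPKM, while AW112010, Clca2 and Wfdc13 fell 10.99-fold, 14.9-fold and 37.97-fold. Hspa1a and Hspa1b, Mt1 and Mt2, Acot1, Saa1 and the histone genes have close paralogs, so their values are uncertain where fragments could be split between copies. Ranked without the restriction to values above 0 and at least 200 bases, the 20 largest changes were those of Mt2, Hspa1a, Csn1s1 and Ero1l and of TrnQ, TrnN, TrnW, Snora64, Scarna8, Taf1d, Iah1, Fam118b (higher), Snora28 and 7 unnamed loci (lower), which apart from LOC100862378 were listed at 0 in at least 1 compared library. Without Mtdh-KO library 2, 5 of the 19 genes still tested among the 20 plotted for the largest changes kept their call, without control library 2 it was 7 of 19, and with the 4 tumorsphere libraries fitted alone 11 of 20.

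**Figure D2:**
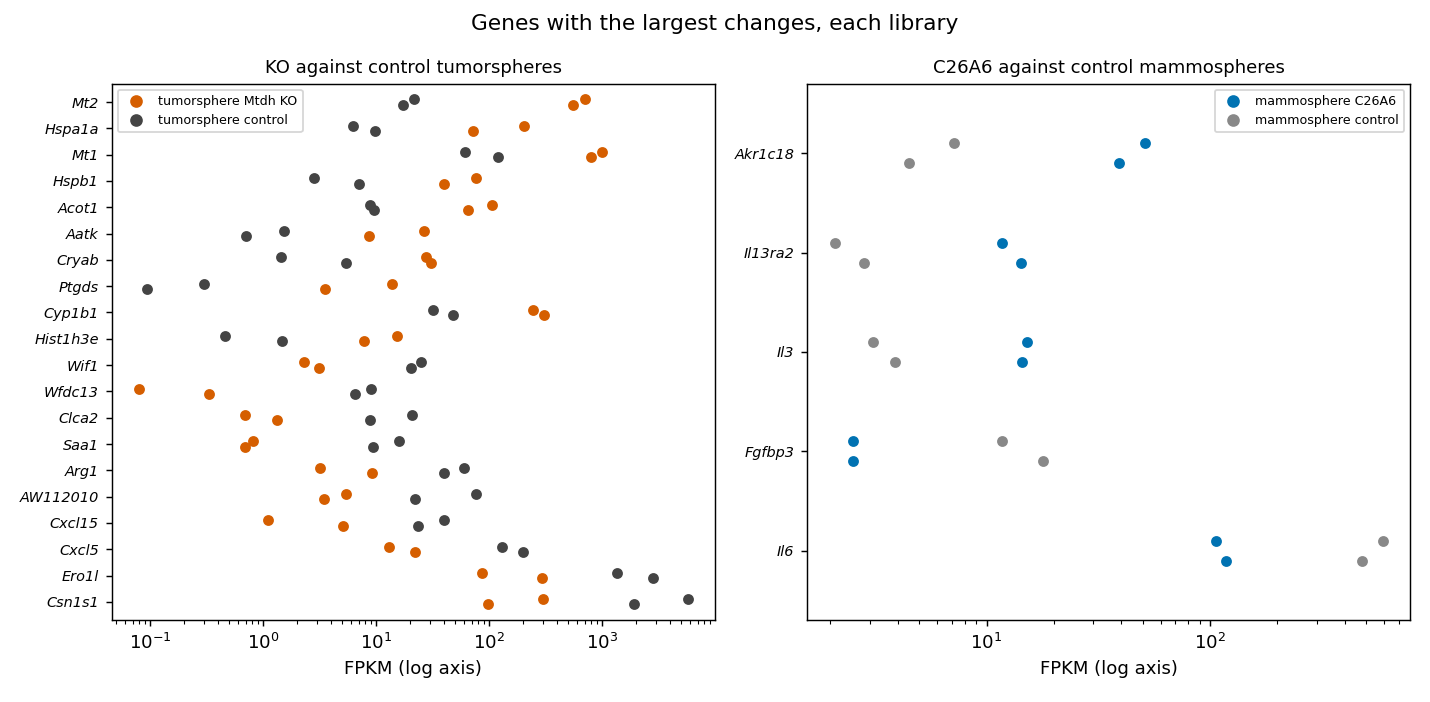
FPKM of each library, on a logarithmic axis, for the genes with the largest log2(FPKM + 1) changes that passed the test and had values above 0 in every compared library, 20 in tumorspheres (left) and 5 in mammospheres (right). Points are single libraries, and for every gene shown the 2 treated libraries lie on one side of the 2 controls, as the rule for naming genes required.

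Interferon response genes were lower in the Mtdh-KO tumorspheres, with 22 of 25 tested members below control (median log2 change -0.54, camera adjusted p = 9.3e-10; adjusted p = 0.50 with an estimated correlation). Of them 3 passed the test, or 8 when adjusted over the list alone. The mean change of the interferon list was -0.71. Its 95% interval from the spread between libraries, -1.68 to 0.27, included 0, and fry did not call the list (adjusted p = 0.26). Ifi44 fell from 219 ± 20.4 to 45.8 ± 8.402 FPKM (adjusted p = 0.011), Ifit1, which binds foreign RNA, from 95.8 ± 8.37 to 20.2 ± 0.642 FPKM, and Oasl2 fell 2.85-fold. The NF-kB and cytokine list was also lower (median -0.14, camera adjusted p = 5.6e-04; adjusted p = 0.50 with an estimated correlation), but its 3 called members moved apart. Cxcl5 fell, the iron-binding Lcn2 fell from 8677 ± 50.8 to 2469 ± 434 FPKM, and Rela, an NF-kB subunit, rose from 4.63 ± 0.324 to 13.5 ± 3.98 FPKM. Adjusted over that list alone, 2 members were higher and 4 lower. The size of the NF-kB median was not settled. It lay between -0.68 (without control library 2) and -0.0041 (without control library 1) over the settings run, and stood at -0.38 and -0.55 in the other scalings. Without Mtdh-KO library 1 it was -0.047 and without Mtdh-KO library 2 -0.35. At the preset correlation the call was kept in each setting. The mean change of the NF-kB list was -0.41, with a 95% interval from -0.92 to 0.10, and fry did not call it (adjusted p = 0.28). The interferon median lay between -0.88 (quantile normalization) and -0.35 (without Mtdh-KO library 1).

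MHC class I antigen presentation was tested because published work on the Mtdh-Snd1 complex concerns it, so the list may not be independent evidence of its direction. None of its 22 tested members passed the test, either over all genes or adjusted over the list alone. The list as a whole lay lower (15 of 22 below control, median -0.18, camera adjusted p = 0.0021; adjusted p = 0.72 with an estimated correlation). Without Mtdh-KO library 1 the call was lost, with an adjusted p of 0.18 and a median of 0.19. The median was -0.50 and -0.33 in the other scalings, -0.083 without control library 2 and -0.49 without Mtdh-KO library 2. Over the settings run the adjusted p lay between 2.1e-05 and 0.18. The mean change of the list was -0.23, with a 95% interval from -1.36 to 0.90, and fry did not call it (adjusted p = 0.83). The peptide transporter genes Tap1 (chromosome 17, 34187556 to 34197225) and Tap2 (chromosome 17, 34204479 to 34216321) stood at 7.05 ± 1.798 and 8.29 ± 0.631 FPKM in control and at 6.26 ± 2.51 and 9.07 ± 2.54 FPKM in Mtdh-KO tumorspheres, with log2 changes of -0.17 (SE 0.48) and 0.10 (SE 0.41) and adjusted p of 0.88 and 0.94. The sign of both changes differed between settings. B2m, the MHC class I light chain, stood at 1068 ± 19.5 and 699.9 ± 132 FPKM (adjusted p = 0.099).

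S phase genes were higher (19 of 20 above control, median 0.59, camera adjusted p = 0.024; adjusted p = 0.72 with an estimated correlation). Mcm5, a subunit of the replicative helicase, rose from 6.15 ± 0.479 to 18.4 ± 4.54 FPKM, and 4 members passed when adjusted over the list alone. That list call was lost at a filter of 5 FPKM (adjusted p = 0.051), without control library 2 (0.092) and without Mtdh-KO library 2 (0.14), with medians of 0.63, 0.65 and 0.54. The median was 0.30 with median-of-ratios scaling and 0.26 with quantile normalization, where the call was kept. Its adjusted p lay between 0.0088 and 0.14 over the settings run. The hormone-sensing luminal list was lower (median -0.66, camera adjusted p = 0.018; adjusted p = 0.50 with an estimated correlation), with Foxa1, a pioneer transcription factor, falling from 54.3 ± 30.5 to 7.74 ± 0.578 FPKM while Prlr, the prolactin receptor gene, rose from 27.5 ± 1.13 to 75.1 ± 10.1 FPKM. Adjusted over that list alone, 1 member was higher and 2 were lower. Its call was lost in both other scalings (adjusted p = 0.061 and 0.074), without control library 1 (0.078) and without Mtdh-KO library 2 (0.14), within a range of 0.0027 to 0.14. The medians in these settings were -0.93, -0.86, -0.61 and -0.33. Apoptosis regulators lay lower relative to all genes (median -0.16, camera adjusted p = 0.034; adjusted p = 0.50 with an estimated correlation). The pro-apoptotic Bmf, 2.98-fold lower, was the 1 member of 14 that passed, also when adjusted over the list alone. The call of the apoptosis list was lost without control library 1 (0.052), control library 2 (0.0502) or Mtdh-KO library 1 (0.14), within a range of 0.016 to 0.14. The medians in these settings were 0.034, -0.13 and -0.028. In the other scalings the median was -0.46 and -0.34. Epithelial genes also lay lower relative to all genes (median -0.12, camera adjusted p = 0.048; adjusted p = 0.72 with an estimated correlation), with 8 of 17 members above control and none past the test in either adjustment. That call was lost in 7 of 17 settings, among them without control library 1 (0.62), Mtdh-KO library 1 (0.10, median 0.14) or Mtdh-KO library 2 (0.094), within a range of 0.0025 to 0.62.

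**Figure D3:**
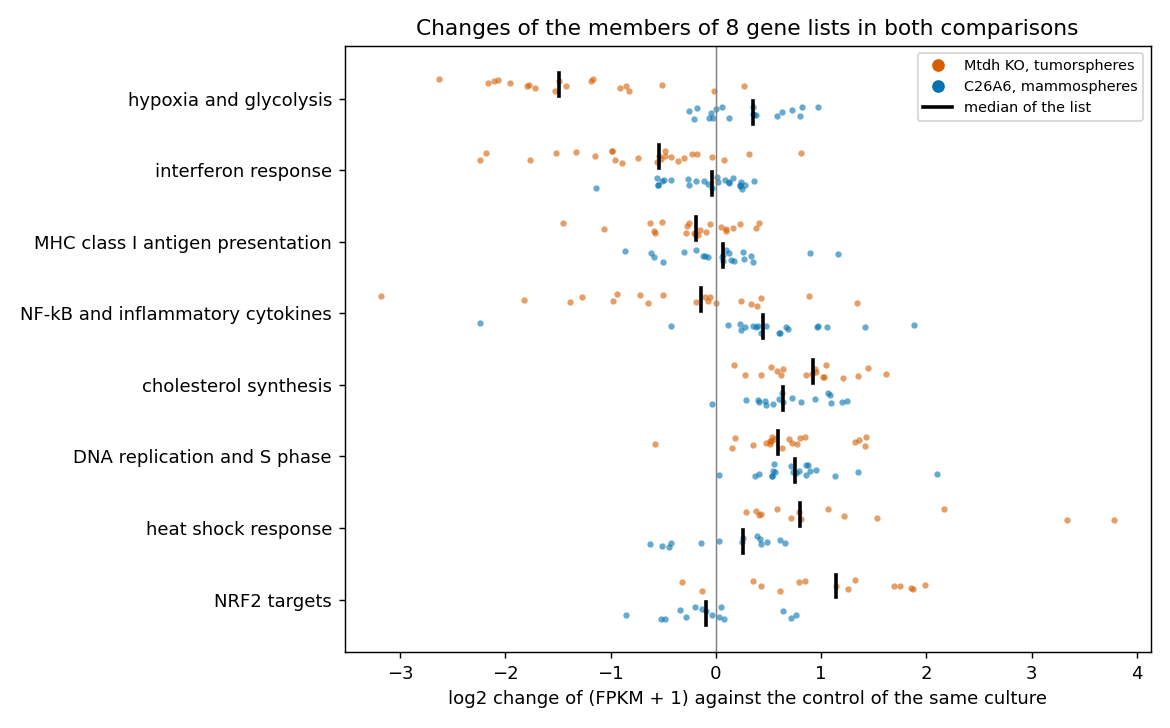
Log2 change of FPKM + 1 against the control of the same culture (horizontal axis) for each tested member of 8 gene lists (vertical axis), where orange points are genes in the Mtdh-KO tumorspheres, blue points the same genes in the C26A6 mammospheres, and black bars list medians. Hypoxia and glycolysis genes had a median of -1.49 in the first comparison and 0.35 in the second, while the medians of cholesterol synthesis (0.93 and 0.63) and of S phase genes (0.59 and 0.75) were above 0 in both.

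In total, 726 of the 13499 genes tested passed an adjusted p of 0.05 in the Mtdh-KO tumorspheres, 533 higher and 193 lower, and 3523 had an unadjusted p under 0.05 against about 675 from chance. Of the 726, 81 were listed at exactly 0 in at least 1 of the 4 libraries and 10 spanned under 200 bases. The share of higher genes depended on the scaling, and the median log2 change over all genes was 0.25 as deposited and 0.016 or -0.016 after median-of-ratios scaling or quantile normalization. The split was 533 higher and 193 lower (73.4% higher) as deposited, 258 and 415 (38.3%) with median-of-ratios scaling and 132 and 166 (44.3%) with quantile normalization. In all 3, 113 higher and 139 lower genes were called. The medians of the hypoxia, interferon, heat shock, NRF2 and cholesterol lists kept their sign in each scaling. With median-of-ratios scaling those of heat shock and cholesterol synthesis fell to 0.48 and 0.59. The count was 111 without control library 1, 53 without control library 2, 102 without Mtdh-KO library 1, 32 without Mtdh-KO library 2, and 192 and 195 without the first and the second control mammosphere library, which share the estimate of the spread. It was 179 with the 4 tumorsphere libraries fitted alone and 298 with quantile normalization.

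The second comparison asked how normal mammary cells respond to C26A6. Cholesterol synthesis and S phase genes were higher as groups. Of 18 tested cholesterol synthesis genes 17 lay above control (median log2 change 0.63, camera adjusted p = 1.3e-05; adjusted p = 0.68 with an estimated correlation), and all 20 tested S phase genes did (median 0.75, camera adjusted p = 1.3e-05; adjusted p = 0.68 with an estimated correlation). No single member of either list passed the test over all genes. Adjusted over the list alone, 8 cholesterol synthesis genes passed and 0 S phase genes did. Without C26A6 library 1 the S phase median was 0.47. Idi1 stood at 46.9 ± 3.87 FPKM in control and 82.99 ± 2.07 FPKM after C26A6 (adjusted p = 0.21), Sqle at 19.9 ± 2.21 and 39.3 ± 2.94 FPKM, and Rrm2, a subunit of ribonucleotide reductase, at 23.4 ± 6.62 and 45.1 ± 1.79 FPKM (adjusted p = 0.27). Over the macrophage and leukocyte markers, 6 of 7 lay above control (median 0.86, camera adjusted p = 0.060), which did not pass. The NF-kB and cytokine list had 18 of 20 members above control (median 0.45, camera adjusted p = 0.060) and did not pass either.

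Among single genes with values above 0 in all 4 libraries, Akr1c18 (chromosome 13, 4132627 to 4150631), which encodes 20-alpha-hydroxysteroid dehydrogenase, rose from 5.81 ± 1.86 to 45.2 ± 8.34 FPKM (log2 change 2.78, SE 0.29, adjusted p = 0.021). Il13ra2, a receptor for interleukin-13, rose 5.29-fold (adjusted p = 0.043) and the cytokine gene Il3 4.201-fold (adjusted p = 0.048). The inflammatory cytokine gene Il6 (chromosome 5, 30013161 to 30019968) fell from 537 ± 80.3 to 112 ± 7.61 FPKM (log2 change -2.24, SE 0.22, adjusted p = 0.015), and Fgfbp3, which encodes a fibroblast growth factor binding protein, fell 5.85-fold (adjusted p = 0.048). None of these 5 calls held when any 1 of the 4 mammosphere libraries was left out, or with a pseudocount of 0.1, and 1 of the 5 held with the 4 mammosphere libraries fitted alone. Over all settings the log2 changes lay between 2.50 and 3.06 for Akr1c18, 1.83 and 2.36 for Il13ra2, and 1.61 and 2.05 for Il3. They lay between -2.46 and -2.09 for Il6 and -2.53 and -1.84 for Fgfbp3. Among the called genes listed at 0 in a whole group were Atp6v1c2, listed at 0 in both controls and at 15.8 and 11.5 FPKM after C26A6, Phtf1 (0 in both, then 10.3 and 9.604 FPKM), Scyl1 (0 in both, then 9.89 and 6.55 FPKM), and Nrm, at 11.7 and 11.1 FPKM in the controls and listed at 0 in both C26A6 libraries. Zeros in these files include genes that all cells use, such as Ubc, and can be failed estimates.

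The cytosolic ribosomal protein and squamous differentiation lists lay lower, with medians of -0.11 and -0.38 (camera adjusted p = 0.047 and 0.047; adjusted p = 0.78 and 0.76 with an estimated correlation), and none of their members passed, including when adjusted over each list alone. The ribosomal call was lost at a filter of 5 FPKM (0.060), with quantile normalization (0.72), and without control library 1 (adjusted p = 0.21, median 0.012) and C26A6 library 2 (0.91, median 0.15), within a range of 1.5e-05 to 0.91 over the settings run. The squamous call was lost in 6 of 17 settings, among them without control library 1 (0.055), control library 2 (0.15) and C26A6 library 1 (0.23), within a range of 7.7e-04 to 0.23. Its median lay between -0.62 and -0.31 over the settings run. The MHC class I list had a median of 0.068 while its test pointed lower relative to all genes (camera adjusted p = 0.31), and none of its 22 members passed, including when adjusted over the list alone. Tap1 stood at 40.1 and 26.2 FPKM in the controls and 50.04 and 18.1 FPKM after C26A6, and Tap2 at 26.3 and 14.2 and 29.9 and 13.7 FPKM (adjusted p = 0.95 and 0.96), with signs that also differed between settings. The first C26A6 library had the highest mean log2 value of all 8 libraries for the MHC class I list (6.22), the interferon list (4.47) and the lymphocyte list (4.73), against 5.27, 3.61 and 3.42 in the second.

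In all, 16 genes passed the test after C26A6, 6 higher and 10 lower, and 1638 had an unadjusted p under 0.05 against about 675 from chance. Of the 16, 11 were listed at 0 in at least 1 of the 4 libraries, and with such genes left out, a choice made after the data were seen, the count was 2, Il6 and Akr1c18. The median log2 change over all genes was 0.17 as deposited and -0.0068 or 0.013 in the other scalings. The split was 5 higher and 10 lower (33.3% higher) with median-of-ratios scaling and 4 and 12 (25.0%) with quantile normalization, against 37.5% higher as deposited. Without control library 2 the count was 10, without C26A6 library 1 it was 9 and without C26A6 library 2 it was 35. It was 37 with no filter on low values and 8 with a filter of 5 FPKM.

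Whether the knockout and the compound moved genes alike was asked across genes. The 2 sets of log2 changes, which share no library, had a Pearson correlation of 0.202 and a Spearman correlation of 0.334 over 13499 genes, which are not independent replicates. Differences between replicates, which hold no treatment, correlated between the control and the treated group of a culture at 0.202 in tumorspheres and 0.197 in mammospheres. A Pearson correlation of 0.202 therefore does not by itself show that the 2 treatments moved genes alike. Over the 11999 genes of at least 200 bases with no value of 0 the Pearson correlation was 0.331. Among the 629 of them called in the Mtdh-KO comparison, and so chosen by that change, it was 0.434. Over all tested genes, leaving out C26A6 library 1 gave 0.115 and leaving out control mammosphere library 2 gave 0.158. Of the called genes, 1 was higher in both comparisons (Phtf1, against 0.237 from independent lists) and 2 were lower in both (LOC100861791 and LOC100861959, against 0.143), while 0 were called in opposite directions. Each of these 3 genes was listed at 0 in both libraries of a group in both comparisons. Tested as a difference between the 2 changes, 30 genes passed, and 1427 had an unadjusted p under 0.05. Cxcl5 fell in the Mtdh-KO tumorspheres and stood at 449 ± 26.1 FPKM in control and 1199.7 ± 86.1 FPKM in C26A6 mammospheres, a difference of -4.59 on the log2 scale (adjusted p = 0.0050). For Mt2 the difference was 3.83 (adjusted p = 0.0050). The share of genes whose difference was positive was 63.3% as deposited (19 and 11), 55.1% with median-of-ratios scaling (27 and 22) and 52.8% with quantile normalization (19 and 17). The count was 15 without control tumorsphere library 2 and 5 without either Mtdh-KO library. At the level of lists, hypoxia and glycolysis (camera adjusted p = 8.1e-17), NRF2 targets (1.9e-06), NF-kB and cytokines (3.3e-05), interferon response (6.1e-05), heat shock (1.3e-04) and macrophage and leukocyte genes (0.033) differed between the comparisons, and cholesterol synthesis (0.63) and S phase (0.41) did not pass. No list passed with an estimated correlation (smallest adjusted p = 0.62) or with fry. For the lists that passed with camera, the fry adjusted p lay between 0.17 (hypoxia and NRF2) and 0.67 (interferon). Cell type, agent and dose all differ between the 2 comparisons.

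Control tumorspheres were last set against control mammospheres, which gives the baseline on which each treatment acted. Fibroblast genes, leukocyte genes and inflammatory cytokines were lower in the tumorspheres, and hypoxia genes were higher. All 10 tested fibroblast genes and all 8 tested lymphocyte genes passed and were lower, with medians of -4.26 and -3.92 (camera adjusted p = 9.4e-10 and 2.4e-05; adjusted p = 0.34 and 0.40 with an estimated correlation). Of 20 genes of the NF-kB and cytokine list 11 were lower and 2 higher (camera adjusted p = 0.0040; adjusted p = 0.45 with an estimated correlation), or 12 and 2 when adjusted over the list alone. The matrix proteoglycan gene Dcn stood at 749.8 ± 81.9 FPKM in mammospheres and 2.14 ± 0.00197 FPKM in tumorspheres, and Il6 (537 ± 80.3 and 1.14 ± 0.309 FPKM), Bgn, Mmp3 and Ccl2 were lower too, each with an adjusted p no larger than the 3.0e-06 of Ccl2. Of 19 hypoxia and glycolysis genes 11 were higher and 0 lower (median 1.62, camera adjusted p = 1.1e-07; adjusted p = 0.39 with an estimated correlation), and Egln3 stood at 10.8 ± 1.36 FPKM in mammospheres and 122 ± 6.68 FPKM in tumorspheres. Of 15 NRF2 targets 13 were lower (camera adjusted p = 1.7e-06; adjusted p = 0.34 with an estimated correlation), among them the cystine transporter gene Slc7a11, at 91.1 ± 11.4 and 3.23 ± 0.0146 FPKM. Of 22 MHC class I genes 9 were lower and 0 higher (camera adjusted p = 0.0030; adjusted p = 0.63 with an estimated correlation), including Tap1 (log2 change -2.07, adjusted p = 0.018). Higher in tumorspheres were the luminal factor gene Foxa1 (41.8-fold), the growth factor gene Pgf (24.6-fold), B4galnt2 (50.3-fold) and the casein gene Csn3 (14.3-fold). Adjusted over each list alone, 10 fibroblast, 8 lymphocyte, 12 hypoxia, 14 NRF2 and 14 MHC class I genes passed, all in the directions given. In total 3464 genes differed, 991 higher and 2473 lower in tumorspheres (28.6% higher), against 1357 and 2355 (36.6%) with median-of-ratios scaling and 1819 and 1636 (52.6%) with quantile normalization. Of 32 lists 17 passed, 0 of them with an estimated correlation (smallest adjusted p = 0.34). That alternative did not call even the fibroblast list, all 10 tested members of which passed, so it can hardly separate lists here. Fry called 16 of the 32 lists, the fibroblast list among them (adjusted p = 3.8e-05). The count was 2210 and 2079 without the first and second control tumorsphere library and 2047 and 2117 without the first and second control mammosphere library. Cell type, oncogene and tissue of origin all differ in this comparison.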

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

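The tests of background reads and of abundant genes below were planned before their results were seen, apart from splitting their joint pattern into detection and median. The tests of depth and of background against the median were chosen only after the results were seen, as were the rule that decides the abundant-gene test and the tests of tamoxifen and of the same-size explanation on hypoxia genes. The fits with other scalings and with a library left out were planned, but their use to decide between explanations of the hypoxia change, with its bounds, was chosen only after the results were seen. The change in Mtdh-KO tumorspheres and the change in C26A6 mammospheres differed for 30 genes and for 6 gene lists, by a test of the difference itself. With an estimated correlation 0 of the 6 lists passed (smallest adjusted p = 0.62), and fry called 0 of them (smallest adjusted p = 0.17, for hypoxia and NRF2). The 2 changes come from different agents in different cells, so a difference cannot be assigned to either.

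Of the 30 genes, 21 were listed at 0 in some library, 5 of them short, and 9 were neither listed at 0 nor short. These 9 were Cxcl5, Mt2, Fgfbp3, Igfbp5, Iigp1, Ube2l6, Gbe1, Smad7 and Rgs2. Igfbp5 had log2 changes of 2.32 in tumorspheres and -0.12 in mammospheres (difference 2.44, SE 0.29, adjusted p = 0.027). The interferon-induced GTPase gene Iigp1 had changes of -2.52 and 0.60 (adjusted p = 0.027), and Ube2l6, which encodes an ISG15-conjugating enzyme, of -2.20 and 0.13 (adjusted p = 0.035). Smad7, an inhibitor of TGF-beta signalling, had changes of -1.80 and 0.06 (adjusted p = 0.038). In a fit without genes listed at 0, chosen only after the data were seen, 5 of the 9 kept their call. They were Cxcl5, Mt2, Fgfbp3, Igfbp5 and Iigp1 (largest adjusted p = 0.041). The calls of Ube2l6 (0.054), Gbe1 (0.054), Smad7 (0.056) and Rgs2 (0.054) were lost there.

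Hypoxia and glycolysis genes were lower in the Mtdh-KO tumorspheres (median -1.49). The scaling between libraries is argued against, since the median was -1.51 or lower in both other scalings, and so is a single library, since the largest adjusted p without any one of the 4 tumorsphere libraries was 3.5e-12 at the preset correlation, although with all libraries and an estimated correlation the adjusted p was 0.50. An effect of disrupting the complex that has the same size in both cell types was tested too. The mean change of the list in C26A6 mammospheres had a 95% interval from -0.52 to 1.09, above the interval of -2.17 to -0.56 in the knockout. That argues against an equal change in both comparisons, but cannot decide whether disrupting the complex acts in both cell types. Action of C26A6 on the complex was not measured. The mean log2 value of the list in control mammospheres (5.58 and 5.48) also already lay near that of the Mtdh-KO tumorspheres (5.76 and 5.34), against 7.21 and 6.60 in control tumorspheres. An effect of tamoxifen or Cre activation cannot be told apart from loss of Mtdh, because 0 groups received tamoxifen without it. A response to Mtdh loss that is particular to these tumor cells therefore stays a hypothesis beside a tamoxifen effect, a smaller effect of C26A6 and a difference in growth or oxygen supply of the spheroids, which the labels do not describe.

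The Mtdh-KO libraries had more genes above 0 and a higher median than their controls. Depth is argued against for the number of genes, since the KO libraries held 0.685 times the effective fragments of the controls. The median over tested genes, on which the most abundant genes weigh less, was 228 and 264 fragments in the KO libraries and 220 and 282 in the controls. By that measure the KO libraries were neither clearly shallower nor clearly deeper. Background reads such as genomic DNA may add detected genes, since the mean FPKM of 1444 olfactory and vomeronasal receptor genes in the lower KO library was 2.61 times that in the higher control, but adding the mean KO level of these genes to every control value moved the median by only 0.0024. A smaller share taken by abundant genes is argued against as the whole cause of the higher library medians. The share outside the 100 most abundant control genes was 65.3% and 66.1% in the controls and 72.4% and 72.2% in the KO libraries. That log2 rise of 0.139 is 37.0% of the shift of the library medians (0.376), under the bound set beforehand. As a part of the rise it cannot be told apart from a broad rise of many genes. The bound did not say which shift it meant, and 0.139 is 56.1% of the median change over genes (0.248), so by that reading the explanation is not excluded. The 100 genes were chosen by their mean in these same controls, so a lower share in any other group is partly built in. The share outside them was 73.7% to 81.0% in the mammospheres. The rise of 0.139 may therefore be overstated.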

How the results depend on the processing

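The 2 settings that leave out genes listed at 0 or under 200 bases were chosen only after the data were seen. Over the named genes and lists, 735 gene values and 227 list values kept their direction and side of the threshold, 113 and 23 kept only the direction, and 14 gene values and 5 list medians changed sign. These totals pool the comparisons and include Tap1, Tap2 and Snd1, which passed in no setting of either treatment comparison. The treatment calls were less stable than the baseline calls. With only the 4 libraries compared, 20 of 20 baseline genes kept their call, against 11 of 20 in the knockout and 1 of 5 after C26A6. With no counts, a count-based tool could not be run, and the causes of the changes below were not tested except where fewer libraries or genes entered.

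Genes changed in Mtdh-KO tumorspheres numbered 726, against 298 with quantile normalization, 179 with 4 libraries and 32 (without Mtdh-KO library 2) to 720 with 1 library left out. The C26A6 count of 16 became 37 without a filter, 8 at 5 FPKM, 2 without genes listed at 0 and 9 (without C26A6 library 1) to 35 (without C26A6 library 2) with 1 library left out. The difference count of 30 became 49 without a filter, 49 with median-of-ratios scaling, 5 without genes listed at 0 and 5 (without either Mtdh-KO library) to 36 with 1 library left out. The baseline count of 3464 became 2047 (without control mammosphere library 1) to 3625 with 1 library left out. Lone libraries were assumed to vary like the other groups. The Mtdh change of -1.77 lay between -1.90 and -1.64 with 1 library left out, with the call lost as given in the report.

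The 11 lists called in the knockout became 8 to 11, and the 4 called after C26A6 became 4 to 8, with 1 library left out, the 8 without any 1 of the 4 tumorsphere libraries or without C26A6 library 1. The C26A6 lists were 8 with 4 libraries and 11 without genes listed at 0. With an estimated correlation 0 lists were called in either comparison. The baseline fibroblast list was not called by it either, so that setting can hardly separate lists here. That list was called by fry (adjusted p = 3.8e-05). Fry, which does not compare a list with other genes, called 7 lists in the knockout and 0 after C26A6 (smallest adjusted p = 0.18). Of the 11 called by camera these were hypoxia, NRF2, heat shock and cholesterol synthesis (each 0.04997). The others were the xenobiotic (0.04997), estrogen receptor (0.045) and basal (0.045) lists. Interferon (0.26), NF-kB (0.28), MHC class I (0.83), S phase (0.077), apoptosis (0.48), epithelial (0.85) and hormone-sensing luminal (0.23) genes were not called. The correlation of the 2 changes, 0.202, was 0.311 with 4 libraries per fit, 0.316 without genes listed at 0, 0.291 without short genes and 0.115 to 0.229 with 1 library left out.

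The gene values that changed sign never passed the test. Median-of-ratios and quantile scaling gave Tap2 -0.22 and -0.23 and Snd1 -0.23 and -0.13 in the knockout, and Tap2 -0.15 and -0.065 after C26A6. With 1 library left out, knockout values ran from -0.53 to 0.19 for Tap1 (0.06 without control library 2), -0.16 to 0.35 for Tap2 and -0.077 to 0.27 for Snd1, and C26A6 values from -0.81 to 0.61 for Tap1 (0.20 without control library 1) and -0.47 to 0.60 for Tap2 (-0.36 without control library 2). The medians of 4 lists that had passed also changed sign with 1 library left out, with the call lost and the test still pointing lower relative to all genes. In the knockout they ran from -0.49 to 0.19 for MHC class I, -0.20 to 0.034 for apoptosis regulators and -0.17 to 0.14 for epithelial genes, and after C26A6 from -0.43 to 0.15 for ribosomal proteins (0.012 without control library 1).

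The replicate numbers are shared between groups, but with 2 pairs per culture they cannot be taken as pairing the samples. Differences between replicates correlated at 0.202 in tumorspheres and 0.197 in mammospheres across genes. With a replicate block the counts were 1309 in the knockout (705 shared with the 726), 10 after C26A6 (9 shared with the 16, among them 1 of the 5 with no value of 0), 36 for the difference (20 shared with the 30) and 3340 for the baseline. The block gave 10 lists in the knockout and 9 after C26A6.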

Other observations

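For the cholesterol synthesis and S phase genes the fits with other scalings and with a library left out were planned. Their use to decide between explanations, and the tests of leukocytes and of a shared effect, were chosen only after the results were seen. Single members of several other lists passed the test in the Mtdh-KO tumorspheres, while the lists did not pass with camera. Of the integrated stress response genes Atf3 rose from 3.39 ± 0.0575 to 21.8 ± 10.6 FPKM (adjusted p = 0.026), Chac1, which degrades glutathione, 5.96-fold and Trib3 3.82-fold, while the endoplasmic reticulum gene Sdf2l1 fell 2.33-fold, and the list of 21 did not pass (camera adjusted p = 0.38). Among fatty acid synthesis genes Acly rose 2.44-fold, Fads1 2.88-fold and Elovl6 1.97-fold (list adjusted p = 0.26). Of the estrogen receptor list Areg, an EGF receptor ligand, rose 3.32-fold and Ctsd 2.41-fold (list adjusted p = 0.20 with camera and 0.045 with fry). Called genes of mammary differentiation went both ways. The casein genes Csn3 and Csn1s1 fell, Csn3 from 2902 ± 295 to 626 ± 236 FPKM, and Btn1a1, a milk fat globule gene, rose 4.83-fold, while the luminal progenitor genes Elf5, an alveolar transcription factor, and Cd14 rose 2.96-fold and fell 3.32-fold. Serpine1, the plasminogen activator inhibitor, fell from 71.9 ± 28.1 to 12.6 ± 4.602 FPKM, while the other 17 tested mesenchymal genes did not pass.

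Cholesterol synthesis and S phase genes were higher in the C26A6 mammospheres. The scaling and the first C26A6 library are both argued against as the cause, since the largest adjusted p of the 2 lists was 1.0e-05 in the other scalings and 7.2e-05 without that library. A larger share of leukocytes cannot be told apart, because the lymphocyte list had a mean change of 0.18 with a 95% interval from -1.28 to 1.64, while the macrophage list had one of 0.57 (0.09 to 1.05). An effect of disrupting the complex that both cell types share may be a candidate explanation, since both lists were also higher in the Mtdh-KO tumorspheres (larger adjusted p = 0.024, that of S phase, which was lost in 3 settings with 0.051, 0.092 and 0.14 and was 0.077 with fry), but that was seen before the test was written, and no list passed with an estimated correlation. Only the Mtdh-KO tumorspheres received tamoxifen, so the rise of both lists there cannot be told apart from an effect of tamoxifen or Cre activation. Whether the compound acts on Mtdh-Snd1 in the mammospheres was not measured.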
